A study of Zea mays with 12 samples.

How the data were processed

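RNA was measured by sequencing in 12 libraries of maize primary roots, 3 biological replicates for each of 4 groups given by root side (air or contact) and zone (competent, 0 to 5 mm from the tip, or fixed, 5 to 15 mm). Per the labels' protocols, ribosomal RNA was removed from total RNA and libraries were made with a directional kit. The submitters' processing notes name cutadapt 1.3, TopHat2 2.0.9, Cufflinks 2.1.1, Cuffdiff 2.2.1, SAMtools 0.1.19, HTSeq 0.5.4p3 and DESeq2 1.14.0 and the genome build B73 RefGen_v3. The role and settings of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. Values of overlapping and antisense genes, and of near-identical copies such as histone, ribosomal protein, aquaporin and glutathione transferase genes, are therefore uncertain.

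The deposited table gives, per the file headers, an estimated count of fragments per gene locus and library, not scaled, of which 99.66% of the values above 0 lay within 0.001 of a whole number. It also gives FPKM values, scaled per library by the authors, per the file headers. The authors' deposited table of significant genes gives a log2 fold change of contact over air, and an adjusted p-value by the authors, with the algorithm (Cuffdiff2, DESeq2 or paired-sample DESeq2) named per gene. The estimated counts were rounded to whole numbers for all count tests.

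The total counts of replicates 0, 1 and 2 were 10920860, 12229375 and 6794525 in Air Competent, 3971179, 1366503 and 11990402 in Contact Competent, 4537425, 7861507 and 9396155 in Air Fixed, and 5771083, 4334211 and 5666873 in Contact Fixed. A count of 0 allowed up to 3 counts, or 0.245 to 2.20 CPM depending on the library. The 20 genes with most counts held 4.83% to 6.11% of the counts in the competent zone and 7.93% to 9.61% in the fixed zone. Counting intervals and floors cover counting error only. Replicates of a group differed by more than sampling noise in each pair (chi-square per degree of freedom 4.79 to 30.7), with Spearman correlations of 0.934 to 0.979.

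Of 109419 loci, 66890 had no count in any library, and 24666 passed edgeR's filterByExpr and were tested, which held 99.65% of the counts. Differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on TMM-scaled counts, with the 4 group means fitted to all 12 libraries, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were contact minus air in each zone, the difference between these contrasts (competent minus fixed), and fixed minus competent over both sides, in air and in contact. Adjusted p-values of genes in the text are from this test unless another tool is named. Levels are TMM-scaled CPM as mean ± SD of 3 libraries. The SE of a log2 change was its size divided by the square root of the test's F statistic. It can be too small for genes near 0 counts in a group. Fold changes against a group at 0 were computed against a floor of 3 counts over the group.

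Alternatives fixed before the data were examined were DESeq2's size factors in edgeR, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and on log2(FPKM + 0.1), the replicate number as a block, library sizes without the highest 20 genes, only the libraries of the groups compared, other thresholds and leaving out each library. Library sizes could not leave out organelle genes by chromosome, since coordinates were not used here, and left out the loci of the authors' ATP synthesis category in their place. Alternatives chosen after seeing the data were leaving out Air Competent replicate 1 and Contact Competent replicate 0, a surrogate variable (sva 3.50.0), the replicate block within the fixed zone alone, and thinning of the fixed-zone libraries that were deeper than the competent-zone library of the same side and number to its depth.

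The replicate numbers come from the labels. Deviations of libraries from their group means were correlated over 5905 genes above 5 log2 CPM. Between the sides of the fixed zone, same-numbered libraries had correlations of 0.122, 0.23 and 0.37. Differently numbered libraries had correlations of -0.27 to 0.0617. With 3 libraries per group and genes that are not independent, this goes with a pairing by number but does not establish it. In the competent zone the correlations of same-numbered libraries were -0.644, -0.407 and -0.011. Same-numbered libraries did not deviate together there, which does not exclude a pairing.

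Gene lists were fixed before the data were examined. Of 22 lists, 17 had at least 5 tested members and were tested with camera (limma) at a preset correlation of 0.01 between genes and again with an estimated correlation: abscisic acid, aquaporins, auxin, cell cycle, cell wall loosening, class III peroxidases, ribosomal proteins, ethylene, gibberellin with cytokinin and brassinosteroid, heat shock, jasmonate, lignin, low oxygen, nutrient uptake, oxidative stress, defence, and phloem and xylem. Lists for lateral roots, photosynthesis, the root cap and root hairs had fewer, and the endodermal barrier list matched no symbol. Each called list lost its call with an estimated correlation. List median and mean differed in sign between the sides of the fixed zone for jasmonate, oxidative stress, and phloem and xylem, in the competent zone for abscisic acid, cell wall loosening, gibberellin and heat shock, for the interaction for oxidative stress, and for zone for cell wall loosening. For the interaction of cell wall loosening, the median and mean were below 0 and the test pointed up.

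Names came from a reference table of the assembly Zm-B73-REFERENCE-NAM-5.0, which differs from the build of the counts, so that none of its coordinates were used. It matched 18768 loci (14964 of those tested), of which 2661 had a name (2038 of those tested). List members were matched by symbol and older symbol only, and 11 hits on loci shared by more than 1 record were left out, of 518 such loci. Descriptions came from the authors' deposited table, so the naming of genes favours those that the authors listed. The genes named were those with adjusted p under 0.05, a mean of at least 1 CPM, replicates that did not overlap and a name or description, taking the 6 largest rises and 6 largest falls, and in each list the 2 members with the smallest p among those that passed. Where fewer than 5 genes passed, the 5 annotated genes of smallest p were named as not passing, and in a list without a called member the member of smallest p. The result of 1 gene that this rule names is not reported here.

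The tests were run on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For the side difference of the competent zone (24337 genes), edgeR recovered 26% of the 2-fold and 82% of the 4-fold changes, with 52 calls among unchanged genes, more than the threshold allows. For that of the fixed zone (24387 genes) it recovered 15% and 82%, with 3 calls among unchanged genes. In the simulation the shifted ribosomal list was called and 0 of 16 other lists. Each gene was drawn independently there, whereas the estimated correlation within the ribosomal list was 0.42 in the data. The simulation therefore cannot show how often lists of correlated genes are called in error. It also held no structure shared among genes, whereas a split of the competent-zone libraries across the sides called 672 genes in the data. Its recovery rates may therefore not hold for that zone.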

Results

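Gene expression was measured in primary roots of maize seedlings of the inbred line B73 that had grown along the surface of an agar plate, so that a side of each root touched the wet medium and the opposite side faced air. Roots were cut lengthwise into an air side and a contact side, and across into a segment 0 to 5 mm from the tip (the competent zone) and a segment 5 to 15 mm from the tip (the fixed zone). Each of the 4 combinations of side and zone had 3 libraries, numbered 0, 1 and 2, each made from the pooled tissue of 2 seedlings at day 3 after imbibition. The 12 libraries held between 1366503 counts (Contact Competent replicate 1) and 12229375 counts (Air Competent replicate 1), a ratio of 8.95. Of 109419 gene loci, 24666 had enough counts to be tested. The study's title names the perception of water availability in the patterning of root branches as its subject, and the comparisons below ask which transcripts differed between the sides in each zone and between the zones.

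The zone was the main source of variation. The first principal component held 81.9% of the variance and placed the Competent libraries between -175.1 and -120.2 and the Fixed libraries between 130.2 and 166. Within the fixed zone the sides were separated on this axis, with Contact Fixed libraries between 130.2 and 141.9 and Air Fixed libraries between 161.7 and 166. The competent-zone libraries of both sides overlapped on it. The typical variation between replicates, as a biological coefficient of variation, was 28% in the competent zone and 19.2% in the fixed zone.

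**Figure D1:**
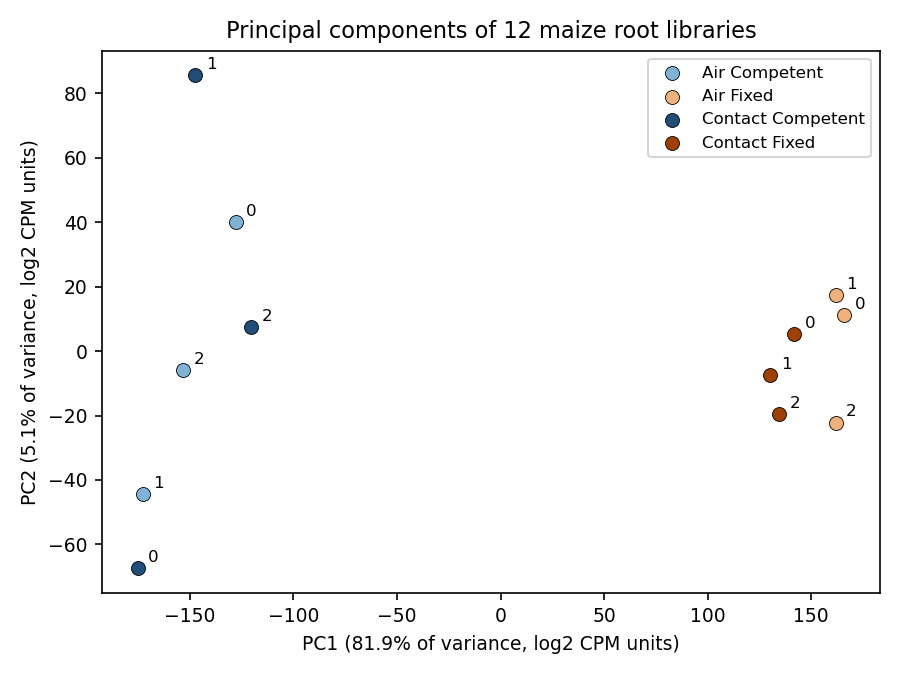
Principal components of log2 CPM for the 12 libraries, with PC1 (81.9% of the variance) on the horizontal and PC2 (5.1%) on the vertical axis, a point per library coloured by group and marked with its replicate number. The zones lie apart on PC1, and the Contact Fixed libraries (130.2 to 141.9) lie nearer to the competent zone than the Air Fixed libraries (161.7 to 166).

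In the fixed zone, the transcripts that were higher on the contact side included genes of ethylene synthesis, nutrient assimilation, crown root formation and the ribosome. ACO (GRMZM2G072529), an oxidase that makes ethylene from its precursor, rose from 1.05 ± 0.275 to 9.06 ± 2.65 CPM (counts scaled to library size, SD, n = 3), a log2 change of 3.05 ± 0.42 (SE). The AP2/EREBP transcription factor EREB27 (GRMZM2G084264) rose by 2.55 ± 0.39, from 2.05 ± 0.679 to 12 ± 3.12 CPM. The LOB domain gene rtcs1 (GRMZM2G092542), which is needed for the formation of crown and seminal roots, rose from 6.02 ± 3.03 to 28.9 ± 7.68 CPM (log2 change 2.21 ± 0.38). On the air side, gols2 (GRMZM5G872256), a galactinol synthase, was at 16.6 ± 2.11 CPM against 2.67 ± 1.22 on the contact side (log2 change -2.60 ± 0.41). A total of 400 genes passed the edgeR quasi-likelihood test, of which 313 were higher and 87 lower on the contact side, and 267 of them differed at least 2-fold. The share of higher genes, 78.25% here, was 69.97% by DESeq2, 63.59% of 1063 genes with the 6 fixed-zone libraries alone and 56.21% of 2763 genes when the replicate number was added to that fit as a block, an alternative chosen after seeing the data. Adjusted p was 0.0184 for ACO, EREB27 and GLN6 and 0.0271 for rtcs1 and gols2.

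Further genes with large rises on the contact side of the fixed zone were GRMZM2G180080 (a mitochondrial protein, 2.88 ± 0.44 on the log2 scale), gst8 (a glutathione transferase, 2.55 ± 0.56), the cytochrome P450 gene GRMZM2G161169 (2.44 ± 0.47) and K1 (GRMZM2G171279, 2.43 ± 0.50). The largest falls were those of the transferase gene GRMZM2G156004 (-3.84 ± 0.80), the cytochrome P450 gene GRMZM2G470442 (-3.67 ± 0.51, from 14.7 ± 4.37 to 1.08 ± 0.95 CPM), a C-4 methylsterol oxidase (GRMZM2G066321, -2.51 ± 0.50), a peroxisomal ascorbate peroxidase (GRMZM2G004211, -2.16 ± 0.40) and an early light-induced protein (GRMZM2G425728, -2.16 ± 0.40). Adjusted p for these genes lay between 0.0131 and 0.0472. The gene with the smallest p of all, AC234163.1_FGT002, lay outside the naming rule and was chosen after its values were seen. The authors' deposited table gives its ortholog as cinnamyl alcohol dehydrogenase 8, an enzyme class of lignin monomer synthesis. It rose from 0.851 ± 0.249 to 23.5 ± 6.95 CPM (log2 change 4.71 ± 0.39, adjusted p = 0.000566).

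**Figure D2:**
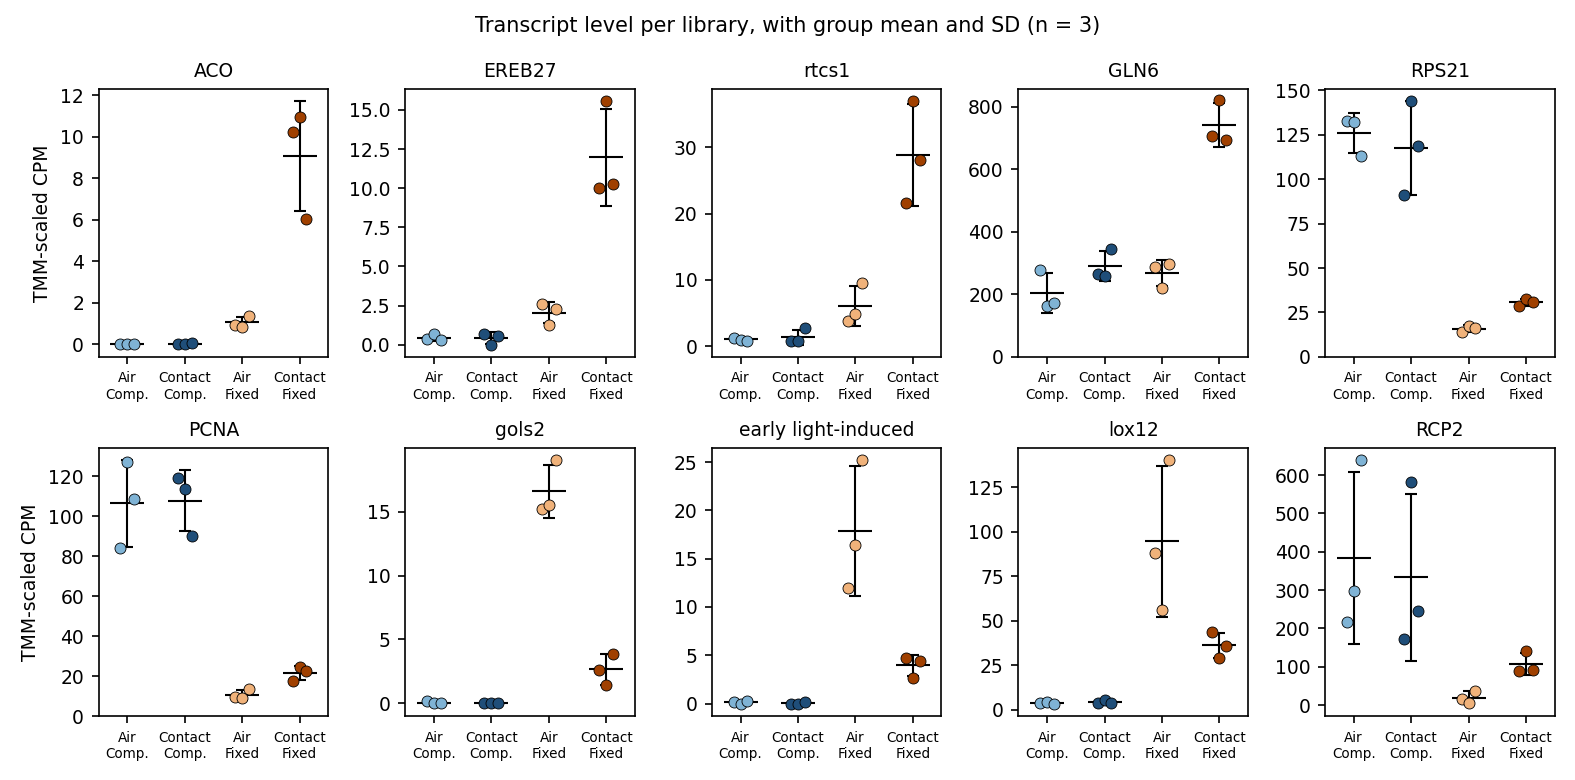
Transcript level in TMM-scaled CPM (vertical axes, linear, a scale per gene) of 10 genes in the 4 groups, with a point per library, the group mean as a horizontal bar and the SD as whiskers (n = 3). ACO, EREB27, rtcs1, GLN6, RPS21 and PCNA were higher in Contact Fixed than in Air Fixed, and gols2, the early light-induced protein gene and lox12 were lower. The difference of RCP2 did not pass the test (adjusted p = 0.0715).

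Among the gene lists tested against all other genes (camera), 4 of 17 differed between the sides of the fixed zone. For the ribosomal, cell cycle and lignin lists, genes with like zone differences shifted in the same direction, as given below. The test did not allow for this. Of 27 cytosolic ribosomal protein genes, 6 rose on the contact side and 21 did not pass (22 rose when adjusted over the list alone), with 26 positive and a median log2 difference of 0.71 (adjusted p = 1.9e-14, and adjusted p = 0.531 with an estimated correlation). Reads of near-identical ribosomal protein genes can be divided among copies. Examples were rps24 (1.40 ± 0.27, from 15.6 ± 3.97 to 41.7 ± 14 CPM) and RPS21 (0.94 ± 0.17). Of 13 genes for nitrate, ammonium and phosphate uptake and assimilation, 3 rose (7 rose and 2 fell when adjusted over the list alone), with a median of 1.05 (adjusted p = 0.0142, and adjusted p = 0.587 with an estimated correlation). They included GLN6, a root glutamine synthetase that fixes ammonium, at 268 ± 42.5 CPM on the air side and 741 ± 70.4 CPM on the contact side, and the phosphate transporter gene pht1 (2.09 ± 0.43). Of 13 cell cycle and DNA replication genes, PCNA, the sliding clamp of DNA replication, rose from 10.7 ± 2.45 to 21.6 ± 3.60 CPM, and 12 did not pass (2 rose when adjusted over the list alone). The median of this list was 0.29 (adjusted p = 0.041, adjusted p = 0.657 with an estimated correlation and 0.0521 with the replicate number as a block). Its adjusted p was 0.0526 and 0.0518 without Air Competent replicates 0 and 2, 0.0507 and 0.067 without Contact Competent replicates 0 and 1, 0.14 and 0.107 without Air Fixed replicates 0 and 1, and 0.0693 and 0.126 without Contact Fixed replicates 1 and 2. None of 14 lignin and secondary wall genes passed (1 fell when adjusted over the list alone), yet 13 were negative, with a median of -0.32 (adjusted p = 0.00485, and adjusted p = 0.531 with an estimated correlation). The member with the smallest p, the cinnamoyl-CoA reductase gene ccr2, was at 27 ± 15.9 CPM in air and 7.68 ± 2.70 CPM in contact (adjusted p = 0.0581, and 0.0322 with the replicate block).

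The remaining 13 lists did not pass as sets. Of 27 ethylene synthesis and response genes, 3 rose (5 rose and 1 fell when adjusted over the list alone, list adjusted p = 0.107), and of 18 auxin response and transport genes, AUX1 (GRMZM2G000158) rose by 1.62 ± 0.36 (4 rose when adjusted over the list alone, list adjusted p = 0.0514). The auxin list passed without Air Competent replicate 1 (0.0466), Air Fixed replicate 0 (0.0116), Contact Competent replicate 2 (0.0445), Contact Fixed replicate 0 (0.0483) or Contact Fixed replicate 2 (0.037). The adjusted p of AUX1 was 0.0473, and 0.0549 with the replicate block. In the jasmonate and wound response list, 1 of 29 genes rose and 3 fell (1 and 4 when adjusted over the list alone), among them lox12, a lipoxygenase gene (-1.39 ± 0.27), and aoc1, an allene oxide cyclase gene of jasmonate synthesis (-0.66 ± 0.14). In the oxidative stress list, 2 of 36 rose and 1 fell, with the same counts over the list alone. The glutathione transferase gene gst31 changed by 1.74 ± 0.35 and gst9 by -1.50 ± 0.33, the latter with adjusted p = 0.0435 and 0.0637 with the replicate block. The P450 gene GRMZM2G161169 likewise had adjusted p = 0.0472 and 0.079 with the block. PYL5, of the abscisic acid receptor family, rose by 1.10 ± 0.19 among 12 abscisic acid and dehydration genes (2 rose when adjusted over the list alone), and the chaperonin gene HSP60-1 rose by 0.92 ± 0.21 among 19 heat shock and chaperone genes (2 rose and 3 fell when adjusted over the list alone).

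No member passed among 21 aquaporins, 14 cell wall loosening genes, 11 gibberellin, cytokinin and brassinosteroid genes, 6 class III peroxidases, 11 low oxygen response genes, 19 pathogen defence and benzoxazinoid genes or 6 genes of the phloem and xylem list. When adjusted over the list alone, 1 aquaporin and 1 cell wall loosening gene rose, 1 hormone gene rose and 2 fell, 5 defence genes fell, and 0 passed in the other lists. The defence list had an adjusted p of 0.212, and of 0.0486 without Air Fixed replicate 1. The aquaporin with the smallest p was NIP2-1 (1.48 ± 0.37, adjusted p = 0.0643, and 0.0319 with the replicate block). expB5, a beta-expansin gene, had 0 counts in all Air Fixed libraries and 25 counts in Contact Fixed, at least 10.8-fold higher against a floor of 3 counts over the group (adjusted p = 0.0591). Other members with the smallest p were RR6 (-0.76 ± 0.18, adjusted p = 0.0566), PER2 (1.54 ± 0.76, adjusted p = 0.343), sus2 (-0.93 ± 0.28, adjusted p = 0.11), BX5 (-1.10 ± 0.30, adjusted p = 0.0762) and NAC76 (2.23 ± 0.79, adjusted p = 0.17). Some of these members passed without 1 library: NIP2-1 (0.0162) and PER2 (0.0254) without Air Fixed replicate 2, expB5 without Air Competent replicate 0 (0.0265) or Air Competent replicate 2 (0.0374), and RR6 without Air Competent replicate 0 (0.0275). The phloem and xylem list held NAC genes picked up by their symbols, so it does not stand for vascular cells.

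Lists with fewer than 5 tested members were read gene by gene. The root cap genes RCP1 and RCP2 were at 9.66 ± 7.31 and 19.9 ± 16.5 CPM in Air Fixed and at 42.4 ± 9.88 and 108 ± 29.3 CPM in Contact Fixed, differences that did not pass (adjusted p = 0.0979 and 0.0715, the latter 0.0416 without Air Fixed replicate 2). The same held for rum1-like1 (0.45 ± 0.17, adjusted p = 0.191), the root hair genes rth3 (0.53 ± 0.18, adjusted p = 0.16) and RHL2 (0.14 ± 0.22, adjusted p = 0.82), and lhcb6, lhcb7 and psat1 of the photosynthesis list (adjusted p = 0.937, 0.56 and 0.134), of which psat1 encodes an enzyme of serine synthesis. The endodermal barrier list matched no gene name. Over the alternatives, RCP2 did not pass in 19 of 25 and passed in the others.

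The fixed-zone count depended on single libraries. Without Air Fixed replicate 0, Air Fixed replicate 1, Contact Fixed replicate 1 or Contact Fixed replicate 2 it was 8, 9, 5 and 16 genes, of which 62.5%, 44.4%, 40% and 81.25% were higher in contact, so that ACO (adjusted p 0.125), EREB27 (0.125), rtcs1 (0.152), GLN6 (0.125), gols2 (0.139), PCNA (0.208) and RPS21 (0.159) no longer passed without Contact Fixed replicate 1. The same held for each other called gene that the naming rule gave for the fixed zone, with AUX1 highest (0.229), and all of these also lost the call without Air Fixed replicate 0, with HSP60-1 highest (0.182). With Air Fixed replicate 0 or 1 or Contact Fixed replicate 1 or 2 left out, 3048, 3299, 2668 and 3077 genes had an unadjusted p under 0.05 by edgeR. With all libraries it was 3986, where 1233 would be so by chance. Over the alternatives, log2 changes were 2.27 to 3.32 for ACO, 2.15 to 2.73 for EREB27 and 2.01 to 2.72 for rtcs1. They were 1.34 to 1.55 for GLN6, 0.88 to 1.21 for PCNA, 0.87 to 1.01 for RPS21 and -2.98 to -2.2 for gols2. Without Air Fixed replicate 2 or Contact Competent replicate 1 the fixed-zone count was 257 and 254, and without Air Competent replicate 0 it was 669. It was 1029 by DESeq2, 535 by limma on log2(FPKM + 1), 32 by limma on log2(FPKM + 0.1), 1050 with no filter on low counts and 1063 with the 6 fixed-zone libraries alone, while the replicates of the sides did not overlap in 25.7% of all tested genes (10% by chance).

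The competent zone showed no gene that passed the same comparison. The edgeR test called 0 genes, 431 had an unadjusted p under 0.05 where 1233 would be so by chance, DESeq2 called 2 and limma 0. The annotated genes with the smallest p were GRMZM2G152958 (a dihydrolipoyl dehydrogenase, at 12.3 CPM in air and 1.23 CPM in contact, log2 difference -3.26 ± 0.62), the receptor-like kinase gene GRMZM2G021624 (1.63 ± 0.36), a type 2 metallothionein (GRMZM2G130173, 1.76 ± 0.43), the glutathione transferase GRMZM2G052571 (1.63 ± 0.41) and cc10, which had 0 counts in air and 10 in contact (5.56-fold higher against the same floor). The level of cc10 was 0.236, 0 and 0.705 CPM in Contact Competent replicates 0, 1 and 2, so this fold rests mostly on replicate 2. Adjusted p was 1 for each of these genes. GRMZM2G152958 passed with no filter on low counts (0.00391) and by DESeq2 (0.0353), with 0.721 to 1 in its other alternatives.

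The genes that led the fixed zone had these levels on the sides of the competent zone. ACO was at 0 and 0.0261 ± 0.0452 CPM, EREB27 at 0.428 ± 0.2 and 0.419 ± 0.372 CPM, PCNA at 106 ± 21.6 and 108 ± 15.3 CPM and rtcs1 at 1.02 ± 0.242 and 1.36 ± 1.13 CPM in air and contact. GLN6 was at 204 ± 64.1 and 290 ± 48.4 CPM (0.51 ± 0.22, adjusted p = 1). All 17 lists had an adjusted p of 0.183 or more, with 0 members called in each, also when adjusted over the list alone. The class III peroxidases had the highest list median (0.69, adjusted p = 0.183, and a median of 0.31 without a member of at most 3 counts per side), with PER42 as the member of smallest p (1.07 ± 0.54). Members of smallest p in other lists were PYL7 (0.29 ± 0.18), PIP1-5 (0.60 ± 0.35), TPS17 (1.05 ± 0.55), expa1 (-0.62 ± 0.40) and gst2 (0.45 ± 0.29), none of which passed. Without Air Competent replicate 0, 5 lists were called (adjusted p from 0.0226 to 0.0308), and without Contact Competent replicate 1 the auxin list was called (0.0429). Replicates of the sides did not overlap in 3.34% of genes (10% by chance), and without Contact Competent replicate 2 the test called 3 genes.

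The side difference was compared between the zones by an interaction term. No gene passed the edgeR test (0 called, 2105 with unadjusted p under 0.05, smallest adjusted p = 0.225), against 132 by DESeq2 and 0 by limma. The genes with the smallest p were a beta-galactosidase (GRMZM2G038281, competent minus fixed -1.10 ± 0.18), GRMZM2G180080 (-2.95 ± 0.51), the leucine-rich repeat kinase gene GRMZM2G131609 (-1.15 ± 0.20), the metallothionein GRMZM2G130173 (2.57 ± 0.50) and GRMZM2G063975, a plasma membrane associated protein (1.96 ± 0.38). Adjusted p was 0.225 to 0.338 for these genes. By DESeq2, GRMZM2G038281 (0.000297), GRMZM2G131609 (0.000371) and GRMZM2G130173 (0.000213) passed, and with no filter on low counts GRMZM2G180080 (0.0132), GRMZM2G063975 (0.0296) and GRMZM2G130173 (0.00707), while the highest adjusted p over the alternatives was 0.777 for each. The beta-galactosidase was at 45.6 and 49.5 CPM in air and contact in the competent zone and at 63.2 and 148 CPM in the fixed zone. As sets, 4 lists differed. The ribosomal proteins had a median of -0.76 (adjusted p = 2.1e-13, and adjusted p = 0.355 with an estimated correlation), with 0 members called and 19 lower when adjusted over the list alone. Lignin and secondary wall genes had a median of 0.45 (adjusted p = 0.000976, and adjusted p = 0.355 with an estimated correlation). The defence list (0.53, adjusted p = 0.0469) and the cell cycle list (-0.26, adjusted p = 0.0478) had adjusted p = 0.68 with an estimated correlation and 0.0597 with the replicate block. In the other lists 0 members passed over the list alone, except for 1 lower cell wall loosening gene. The cell cycle list kept its call without Air Competent replicate 0, Air Fixed replicate 2, Contact Competent replicate 0 or Contact Fixed replicate 0 and lost it without each other library (0.0948 to 0.156). The defence list kept it without Air Competent replicate 0, Air Fixed replicate 1, Contact Competent replicate 2 or Contact Fixed replicate 0 and lost it otherwise (0.0512 to 0.126). The auxin list was called without Air Fixed replicate 0 (0.0471) or Contact Competent replicate 2 (0.0443) and the nutrient list without Air Fixed replicate 2 (0.013). Only 2 of the 17 lists were called without Air Competent replicate 1, Air Competent replicate 2, Contact Competent replicate 1, Contact Fixed replicate 1 or Contact Fixed replicate 2. Without Air Fixed replicate 2, Contact Competent replicate 0 or Contact Competent replicate 2 the test called 3, 2 and 3 genes. Across the 24666 genes, which are not independent replicates, the side differences of the zones had a Spearman correlation of 0.0289 (Pearson 0.0867), which was -0.164 and 0.136 without Air Competent replicates 0 and 2, -0.0511 without Contact Competent replicate 0, and 0.102, 0.0951 and 0.0624 without Air Competent replicate 1 and Contact Competent replicates 1 and 2.

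The zones themselves differed in most of the transcriptome. Most aquaporin, lignin and defence genes of the lists were higher in the fixed zone, and most ribosomal protein and cell cycle genes were lower. A flavonol synthase-like gene (GRMZM5G807276) was at 0.164 ± 0.21 and 0 CPM in Air and Contact Competent and at 98.5 ± 19.6 and 44.2 ± 12.9 CPM in Air and Contact Fixed (log2 change 10.33 ± 0.43). Its few counts in the competent zone leave this log2 change less certain than the SE. The glycine-rich protein gene grp3 (GRMZM2G154954) fell from 213 ± 83.5 and 205 ± 86.6 CPM to 0.586 ± 0.211 and 0.618 ± 0.319 CPM (log2 change -8.48 ± 0.37). EXPA5 (GRMZM2G361064), an alpha-expansin that loosens cell walls, fell by 7.01 ± 0.27 on the log2 scale, from 115 ± 40 and 110 ± 9.63 CPM to 0.913 ± 0.31 and 0.899 ± 0.553 CPM. The edgeR test called 18900 genes, 9672 higher and 9228 lower in the fixed zone, of which 12922 differed at least 2-fold. On the air side alone 17208 genes were called (8777 higher, 8431 lower in the fixed zone) and on the contact side 15689 (8069 and 7620).

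Other genes with large rises toward the fixed zone were R-S (GRMZM5G822829, 10.09 ± 0.49), a transferase (GRMZM2G387394, 9.89 ± 0.51), LOL3 and a stress responsive protein. LOL3 (GRMZM2G125314) had 1 count over the competent libraries and 1184 over the fixed libraries, a ratio of 1640 (95% counting interval 294 to 64800). The stress responsive gene GRMZM2G348125 had 2 and 2483 counts, a ratio of 1720 (475 to 14200). Peroxidase 1 (GRMZM2G177792) had 0 and 797 counts and was at least 368-fold higher against a floor of 3 counts over the group. Cel16 (217 counts against 0) and a dihydroflavonol-4-reductase (GRMZM2G152175, 104 against 0) were at least 52.3-fold and 25-fold lower in the fixed zone. The transcription factor genes bZIP89 (-7.14 ± 0.35) and atGRF5 (-6.91 ± 0.52) also fell.

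Of the 17 lists, 9 differed between the zones. Toward the fixed zone, 18 of 21 aquaporins rose (PIP1-3, from 77.4 ± 20.9 to 1053 ± 171 CPM on the air side, and NIP3-1, 2.61 ± 0.16), as did 12 of 14 lignin and secondary wall genes (lac5, 7.28 ± 0.40, and Bm6, 1.52 ± 0.09), 6 of 6 class III peroxidases (PER42, 7.09 ± 0.36, and PER66, 7.17 ± 0.40) and 22 of 29 jasmonate genes (ZIM28, 6.88 ± 0.23, and aoc1, 2.25 ± 0.10). In the oxidative stress list 26 of 36 rose and 5 fell (gst28, 4.35 ± 0.17, and gst41, -6.90 ± 0.25), in the defence list 14 of 19 rose and 1 fell (the chitinase gene chn1, 9.38 ± 0.58, and TPS8, 8.99 ± 0.46) and in the auxin list 13 of 18 rose and 3 fell (AUX15, 3.43 ± 0.18, and AUX6, 1.88 ± 0.11). Of 27 ribosomal protein genes 26 fell and 1 rose (rps4, -2.72 ± 0.13, and RPS21, -2.46 ± 0.12), and 12 of 13 cell cycle genes fell, among them the histone genes his2a1 (-3.78 ± 0.17) and his2b2 (-4.20 ± 0.20). Adjusted p for these 9 lists lay between 1.9e-09 (ribosomal proteins) and 0.0196 (auxin), and between 0.123 and 0.289 with an estimated correlation. Adjusted over the list alone, the counts were equal except in defence, where 15 rose. Adjusted p of the genes named for zone lay between 2.33e-10 (ZIM28) and 0.00585 (lhcb6).

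**Figure D3:**
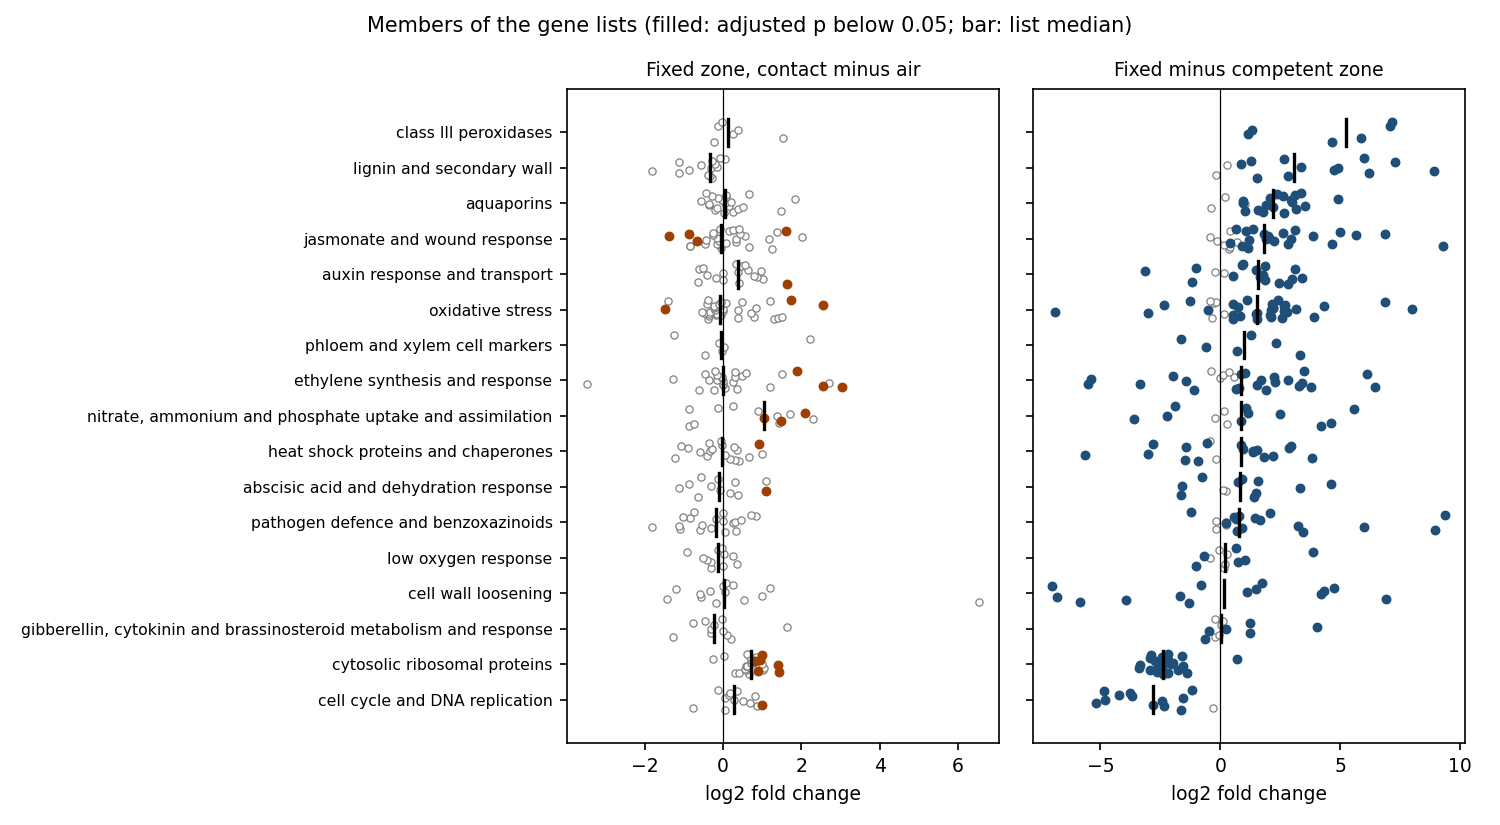
Log2 fold change (horizontal axes) of each tested member of 17 gene lists (vertical axis) between the sides of the fixed zone (left) and between the zones (right), with filled points for adjusted p below 0.05 and a vertical bar at the list median. On the left, 26 of 27 ribosomal protein genes lie above 0 and 13 of 14 lignin genes below it, and on the right 26 of 27 ribosomal protein genes lie below 0. The outermost point on the left is expB5, whose fitted value rests on 0 counts in air.

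The other 8 lists held genes that moved both ways with zone. All 14 cell wall loosening genes changed, 7 up and 7 down (expB2, -3.91 ± 0.20). Rises and falls numbered 16 and 6 of 27 ethylene genes (EREB202, 2.81 ± 0.18, and EREB92, 2.24 ± 0.15, list adjusted p = 0.0639), 7 and 3 of 12 abscisic acid genes (asr1, 4.62 ± 0.29, and PYL2, -1.61 ± 0.10), 7 and 3 of 13 nutrient genes (NRT1.2, 5.58 ± 0.38, and gln2, 4.20 ± 0.19), 10 and 7 of 19 heat shock genes (Hsp70, 2.88 ± 0.17, and HSP60-1, -2.79 ± 0.15), 4 and 2 of 11 low oxygen genes (sus2, 3.89 ± 0.26, and gpc3, -1.01 ± 0.19), 4 and 2 of 11 gibberellin, cytokinin and brassinosteroid genes (RR6, 1.24 ± 0.13, and RR7, 1.26 ± 0.17, with 3 and 1 over the list alone) and 4 and 2 of 6 genes of the phloem and xylem list (sut4, 2.34 ± 0.14, and sut1, 3.32 ± 0.37). Of the short lists, rtcs1 (3.27 ± 0.32), rum1-like1 (1.87 ± 0.12) and lhcb6 (1.33 ± 0.38) rose, and RCP1 (-3.83 ± 0.45), RCP2 (-2.93 ± 0.45), RHL2 (-1.59 ± 0.15), rth3 (-0.57 ± 0.13) and psat1 (-0.94 ± 0.12) fell.

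The side difference in the fixed zone ran against the zone difference. Of the 313 genes higher in contact, 195 fell with zone, 91 rose and 27 did not pass for zone, and of the 87 genes lower in contact, 81 rose with zone, 4 fell and 2 did not pass. Of all 24666 tested genes, 9228 fell and 9672 rose with zone. The 2173 genes with a zone log2 change of -4 to -2 had a median fixed-zone side difference of 0.572 (quartiles 0.145 and 0.9). The ribosomal (zone median -2.38, side median 0.71) and cell cycle lists (-2.80 and 0.29) lay within these quartiles. The lignin list (3.10 and -0.32) lay within those of the 2624 genes at 2 to 4 (-0.48 and 0.223). The nutrient list (0.87 and 1.05) lay above those of the 11584 genes at -1 to 1 (-0.196 and 0.162). Across genes, the Spearman correlation of the side difference with the zone difference was -0.368 in the fixed zone and 0.23 in the competent zone. Over the 400 genes called in the fixed zone alone it was -0.141 (Pearson -0.393). In the competent zone, without Contact Competent replicate 2 it was -0.192, without Air Competent replicate 1 it was 0.0425, and without Air Competent replicate 0 and Contact Competent replicate 0 it was 0.462 and 0.348. Genes are not independent replicates, and no p is given for these correlations. Each side contrast also shares its libraries with the zone contrast, and their errors cancel only where the sides have equal spread. The biological coefficient of variation was 20.8% in Air Fixed and 17.2% in Contact Fixed, and 28.9% in Air Competent and 26.4% in Contact Competent. Part of the correlations may come from this, and its size was not tested. The root cap genes RCP1 and RCP2, which are tip transcripts, were 2.13 ± 0.62 and 2.42 ± 0.63 higher on the contact side of the fixed zone on the log2 scale without passing the test.

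**Figure D4:**
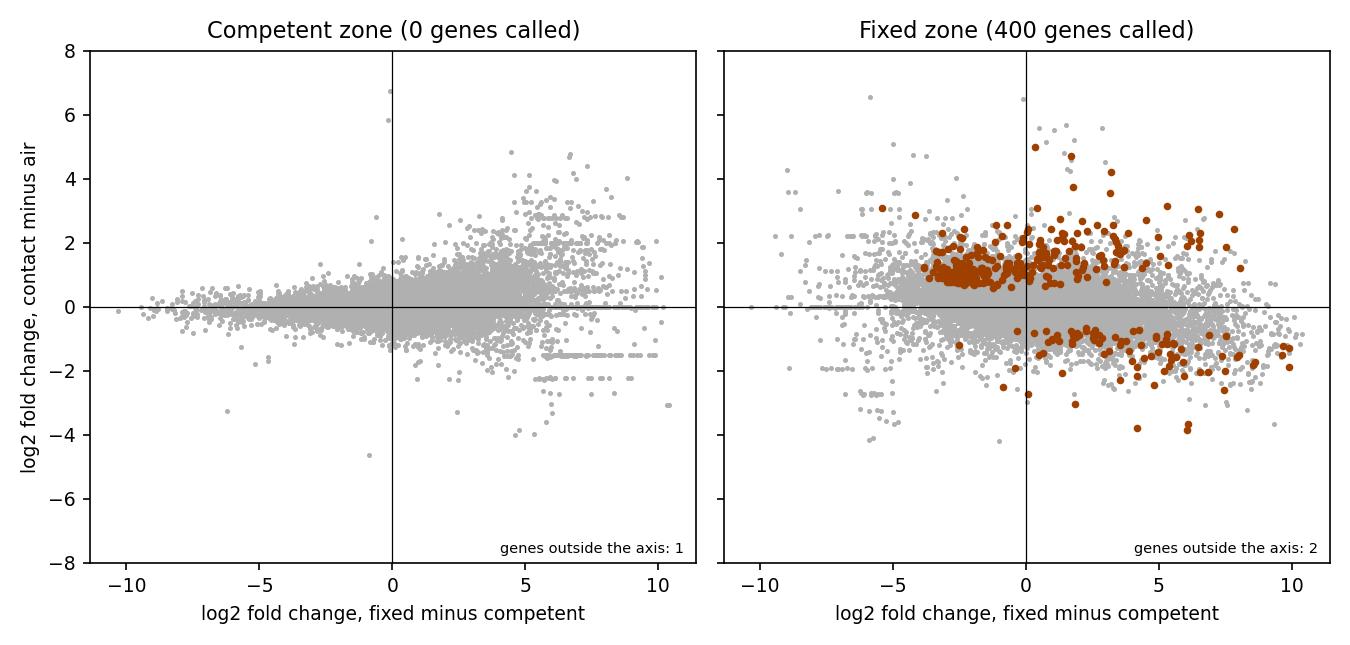
Log2 fold change between the sides (vertical axes, contact minus air) against that between the zones (horizontal axes, fixed minus competent) for 24666 genes in the competent zone (left) and the fixed zone (right), a grey point per gene and orange-brown points for genes with adjusted p below 0.05 between the sides. In the fixed zone, 195 of the 313 genes higher in contact lie left of 0 with a zone difference that passed, and 81 of the 87 lower genes lie right of it. Values of 1 and 2 genes fall outside the vertical axes.

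The authors' deposited table lists 98 genes for the competent zone (67 higher and 31 lower in contact), all by Cuffdiff2, and 1479 for the fixed zone (906 higher, 573 lower) by Cuffdiff2, DESeq2 or paired DESeq2. Of the competent-zone genes in the authors' deposited table, 83 were tested here, 82 had the listed sign, 35 had an unadjusted p under 0.05 and 0 passed. For the fixed zone, 1338 genes of the authors' deposited table were tested, all with the listed sign, and 263 passed. These genes were chosen on the same libraries, so their signs are not independent evidence.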

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

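All tests of explanations in this part were chosen only after the results were seen. So were the thinned counts and the counts of genes and lists over splits of the libraries. The lists, the interaction test and the splits for the correlation with zone were planned.

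The interaction test set apart 4 gene lists, whose median log2 side differences differed between the zones. Genes with zone differences like those of the ribosomal list also differed between the sides of the fixed zone, and the test did not allow for this. For the cytosolic ribosomal proteins the median of the interaction was -0.76, with list medians of -0.04 in the competent and 0.71 in the fixed zone (adjusted p = 2.09e-13, and adjusted p = 0.355 with an estimated correlation). The values were 0.45 for lignin and secondary wall (0.18 and -0.32), 0.53 for defence and benzoxazinoids (0.09 and -0.19) and -0.26 for cell cycle and DNA replication (-0.04 and 0.29). With an estimated correlation these 3 lists had adjusted p = 0.355, 0.68 and 0.68. Without members of at most 3 counts per side in the competent zone, the medians of the lignin and defence lists were 0.45 and 0.48. Of 60 splits of the libraries, 7 gave 4 or more lists, with up to 6, so chance is not excluded for this count. A split that divides the sides of a zone unevenly can keep part of a side difference, so these list counts may not show chance alone. The interaction called 0 genes, which each of the 60 splits equals or exceeds (up to 135), so the splits say nothing of that count.

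Contact Fixed libraries lay toward the competent-zone profile, and of the 313 genes higher in contact 195 fell with zone. Tip tissue of average profile carried into the contact-side segments is argued against as the cause for the 195 genes. A set of 72 genes at least 64-fold lower in Air Fixed than at the tip gained a median of 0.336% of their tip level (90th percentile 2.23%). The 195 genes gained 15.8% (10th percentile 9.59%), though they were chosen as higher in contact on these libraries. The 72 genes also had a median log2 side difference of 0.776, against 1.02, so a small admixture is not excluded. Tissue from next to the cut is not covered. A segment boundary nearer the tip on the contact side stays open, since 91 genes higher in contact rose with zone but levels within a segment were not measured. Detached root cap cells stay open too, with a largest adjusted p of 0.0979 and only 2 markers. A contact-side difference in the pace of maturation, which the design names as side, may also account for the pattern and was not tested; the 6 fixed-zone libraries make 10 splits, too few for a share under 0.05, with 400 genes called by the real split and 0 by the highest other, also among the 3 others that part all pairs, and a correlation with zone of 0.368 in size against 0.242.

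No gene passed between the sides of the competent zone (edgeR 0, 431 at unadjusted p under 0.05, DESeq2 2, limma 0). The competent zone was not shallower as a whole, though Contact Competent replicates 0 and 1 held 3971179 and 1366503 counts. Each of the 3 fixed-zone libraries deeper than the competent library of the same side and number was thinned to its depth. After this, 234 fixed-zone genes passed, so low depth alone did not remove the calls at the fixed zone's differences and spread. The biological coefficient of variation was 28% in the competent and 19.2% in the fixed zone. Low depth together with the larger spread is therefore not excluded as a cause. A structure of the competent libraries along the zone axis that runs across the sides may contribute: the split of Air Competent replicate 0 and Contact Competent replicates 1 and 2 from the other 3 called 672 genes, with a correlation with zone of 0.485 in size against 0.23 for the real split. That split is also the one made by exchanging the replicate 0 labels. An exchange stays open, because the lowest correlation of same-numbered libraries after it was -0.286. As labelled, same-numbered libraries of this zone did not deviate together either. The 10 splits are too few for a share under 0.05 (0 lists by the real split, 4 by the highest other).

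The authors' deposited table lists loci of an ATP synthesis category for both zones. For the fixed zone the median difference in log2 CPM of 6 loci was 2.73, and 0.84 without Contact Fixed replicate 1, in which GRMZM2G066111 was at 519 CPM against 4.8 and 9.2 CPM in the other replicates, so a single library may account for it; by edgeR, with that library included, the median was 4.90, with 5 of 6 at an unadjusted p under 0.05 and 0 passing. For the competent zone the median of 5 loci was -4.65 ± 3.37 (SE over libraries). It was -5.47 ± 5.59, -2.36 ± 1.56 and -7.12 ± 4.13 without Contact Competent replicates 0, 1 and 2. GRMZM2G109332 was at 8.7, 28.1 and 1299 CPM in these replicates. Where replicates 0 and 1 are both low, leaving out 1 library at a time cannot decide whether single libraries account for the difference. GRMZM5G858772 was at 0, 0 and 1128 CPM in Contact Competent replicates 0, 1 and 2, and by edgeR the median log2 difference of the 5 loci was -1.69, with 0 of 5 at an unadjusted p under 0.05. No biological explanation was tested.

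For zone, chance is excluded for the count of 18900 genes (1 of 60 splits, highest other 10939). The splits cannot decide for the 9 lists (15 of 60 splits, up to 11). A split that divides the zones unevenly within a side can keep part of the zone difference. Among the splits of the air libraries, 1 called 0 genes and still 9 lists. For zone in air (17208) and in contact (15689) the 10 splits are too few, with 0 genes for the highest other. For the fixed-zone lists, 3 of 10 splits gave 4 lists, the real split among them, and the other splits can likewise keep part of the side difference. The 3 others that part all same-numbered pairs gave 3, 1 and 2 lists.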

How the results depend on the processing

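Alternatives chosen after seeing the data were leaving out Air Competent replicate 1 and Contact Competent replicate 0 (the lowest on the second component), the surrogate variable, the block within the fixed zone alone and the thinned counts; the others were planned. The zone count of 18900 was 12922 with a 2-fold limit, 15763 at 5 CPM or more and 21013 with no filter, and 18305 to 18981 with a library left out. No named gene that passed changed sign. Of the named fixed-zone gene results, 681 kept their side of the threshold, 173 lost and 44 gained the call. The causes were not tested.

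The competent-zone count was 5 with no filter, 2 by DESeq2 and 0 to 3 with a library left out. The fixed-zone count of 400 was 1050 with no filter, 1029 by DESeq2, 32 on log2(FPKM + 0.1), 1063 with its own libraries only, 1180 at an adjusted p under 0.10, 1083 with the surrogate variable, 234 after thinning and 5 to 669 with a library left out. The interaction count was 51 with no filter, 132 by DESeq2, 1 without this pair of libraries and 0 to 3 with a library left out.

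With the replicate block, the fixed-zone count was 484, and 2763 within the fixed zone alone (396 of the 400 genes shared). The block left 2 interaction lists and 3 fixed-zone lists; beside the gene calls given with the results, it changed no other call. In the competent zone, where same-numbered libraries did not deviate together, the count with the block was 0.

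With an estimated correlation, 0 lists were called in the fixed zone, for the interaction and for zone. Interaction lists numbered 2 without the same pair of libraries and 2 with the surrogate variable. With a library left out, 0 to 5 lists were called in the competent zone, 3 to 5 in the fixed zone and 2 to 4 for the interaction. The correlation between the side differences was 0.33 over genes called in either zone, and -0.164 to 0.136 with a library left out. That with zone in the competent zone was -0.192 without Contact Competent replicate 2, the lowest of a range up to 0.462. In the fixed zone it was -0.415 at 5 CPM or more, -0.405 over zone genes, -0.141 over the 400 called genes and -0.384 to -0.308 with a library left out. The planned fit of zone with only its own libraries is the same fit and was not run. Depth limits low genes most in Contact Competent replicate 1, which held 1366503 counts.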

Other observations

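The gene categories below are those of the authors' deposited table, which were chosen on these libraries, so their directions are not independent evidence, and their genes were chosen here after their values were seen.

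On the contact side of the fixed zone, further genes of hormone and root development passed. RTCN (GRMZM2G092483), a LOB domain gene, rose from 36.9 ± 4.77 to 136 ± 45.3 CPM (log2 change 1.87 ± 0.42, edgeR adjusted p = 0.0475). A GH3 family gene of auxin response (GRMZM2G053338) rose by 1.88 ± 0.27 (adjusted p = 0.0162), a gene with the ortholog gibberellin 2-beta-dioxygenase (GRMZM2G031724) by 2.04 ± 0.46 (0.0473), one with the ortholog expansin-A7 (GRMZM2G127029) by 3.09 ± 0.56 (0.0279) and one with the ortholog HERK1 (GRMZM2G442277) by 1.45 ± 0.29 (0.0353). In the ethylene synthesis category 7 of 7 tested genes were positive and 3 passed, in AP2/EREBP 11 of 11 and 4, and in auxin signaling 11 of 12 and 4.

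Of 12 anthocyanin synthesis genes, 10 were negative and none of these passed, such as the chalcone isomerase gene GRMZM2G175076 (347.8 ± 90 CPM in air and 123.8 ± 32.9 in contact, -1.49 ± 0.35, adjusted p = 0.0542), a2 (-1.24 ± 0.49) and A1 (-1.23 ± 0.57). The other 2 rose in contact: Anthocyaninless4 (GRMZM2G013726, 2.23 ± 0.34, adjusted p = 0.0184) and GRMZM2G162158 (1.25 ± 0.24, adjusted p = 0.0343). In the Casparian strip category 12 of 13 tested genes were negative and 1 of them passed, while the other, AC234163.1_FGT002, passed as higher in contact (4.71 ± 0.39, adjusted p = 0.000566). In light response 6 of 6 were negative and 2 passed, among them a phototropin gene (GRMZM2G032351, -1.58 ± 0.36, adjusted p = 0.0478). Both cuticular wax genes fell (GRMZM2G062946, -2.04 ± 0.39, and GRMZM5G817964, -1.72 ± 0.33).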
